A study of Mus musculus with 11 samples.

How the data were processed

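Gene expression was measured with Affymetrix mouse arrays in total RNA from the left ventricle of adult and newborn mice. The transgenic mice carried a full-length mouse Hmgn5 cDNA behind a floxed LacZ cassette and a cre recombinase driven by the alpha myosin heavy chain promoter, which is active in heart muscle cells. The controls were labelled wild-type. The 11 heart arrays fell into 4 groups: 3 transgenic adult, 3 control adult, 3 transgenic newborn and 2 control newborn arrays, which the labels call biological replicates. RNA was purified on columns with DNase treatment and turned into biotinylated cRNA, per the labels' protocols. RMA, affy and limma are named in the submitters' processing notes, with neither versions nor roles. The values deposited by the authors are on the log2 scale, with 45101 probe sets per array and array medians between 5.12 and 5.18. Nearly equal medians are what RMA gives by quantile normalisation, so a change of most transcripts in 1 direction would not show in these values.

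A probe set takes its gene name from the platform annotation. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none listed. By gene ID, 34754 of the single-symbol probe sets matched the RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols changed. Each gene was represented by the probe set with the highest mean over all arrays among those with 1 symbol, which left 18194 genes, of which 9012 had more than 1 probe set. Some genes fixed in the lists in advance were not among them and are not analysed here. Array data hold no read depth, so the number of arrays limits the precision.

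A group-means model over all 11 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 4 groups share 1 estimate of each gene's spread, with 7 residual and 3.85 prior degrees of freedom. Adult arrays varied more than newborn arrays, and this shared estimate averages over both. It makes adult tests liberal and newborn tests conservative. The 5 contrasts were transgenic against control in adults, the same in newborns, the difference between these effects, and adult against newborn in control and in transgenic hearts. Tests were 2-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, and every adjusted p of a gene below is limma's. Fold changes are differences of group means of log2 values, with limma's moderated standard error. Checked on data simulated with this shared spread over 18194 genes, the adult contrast recovered 23.9% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 98.5% of those changed 4-fold, with 14 false calls. The newborn contrast recovered 19.4%, 71.6% and 97.0%, with 4 false calls. Both ages had the same spread in these simulated data. The simulation therefore cannot show what the wider adult and narrower newborn spread do to recovery or false calls.

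The comparisons, the tests, 36 gene lists and the rule for named genes were fixed before the data were examined. The lists cover heart muscle programmes, metabolism, matrix, chromatin and nuclear envelope, stress responses and markers of other cell types a ventricle sample could hold. Lists with at least 3 measured genes were tested with camera (preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over 35 lists within a contrast; the list of sex-linked genes was not tested. Camera with an estimated correlation and fry were run beside it. Genes were named as follows: the Hmgn5 probe set, then the 12 rising and 12 falling genes with the largest fold change among called genes whose groups of arrays did not overlap. If fewer than 5 genes passed in a direction, the 5 with the smallest p were taken. For each age contrast 8 and 8 genes were taken, for the difference between ages 6 and 6, and for each list up to 4 members with the smallest p per contrast. Names that are only clone or predicted-gene identifiers were counted and passed over. List members named outside these limits were chosen after their values were seen.

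Alternatives fixed in advance were the replicate number as a block, a filter keeping genes above the 40th percentile of the array on at least 2 arrays, all probe sets, the mean of a gene's probe sets, an intensity trend with robust variance, array weights, only the compared groups in the fit, cyclic loess, a common array median, a 1.5-fold threshold and leaving out each array. After the data were seen, 5 more were added: a batch factor, a fit without that batch, the replicate block with the 6 adult arrays alone, the level of atrial markers as a covariate, and sex as a factor. Sex was read from Xist and Y-linked transcripts and was balanced in adults, where replicate 1 of both groups was male and replicates 2 and 3 were female. In newborns, replicate 1 of both groups read as female and the others as male, with Eif2s3y above Xist. Xist on these male-read arrays was 8.08 and 6.90 (transgenic) and 8.65 (control), against 5.44 and 6.13 on the adult male arrays. Their sex is therefore less certain. The sample titles do not say whether RNA of several newborn hearts was pooled. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.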

Results

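Left ventricles of adult and newborn mice were profiled to ask how overexpression of HMGN5 in the heart changes gene expression. HMGN5 is a nucleosome-binding protein that counteracts linker histone H1 in chromatin compaction. Each age held 3 arrays labelled transgenic, beside 3 control arrays in adults and 2 in newborns. Over the 18194 tested genes, pairs of arrays within a group correlated at 0.975 to 0.992 in adults and at 0.994 to 0.997 in newborns. Adult arrays fell into 2 sets by the signal of the 18S ribosomal RNA control probe sets. Replicate 3 of both adult groups read 12.18 (transgenic) and 11.89 (control), against 7.64 to 8.58 in the other 4 adult arrays, and it also had the higher nuclear transcript Malat1 (13.04 and 12.75, against 8.15 to 9.33). This batch held 1 array of each adult group, so adult results are also given without it and with it as a factor. Newborn arrays read 10.05 to 10.53 for 18S, so age and array processing cannot be told apart.

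The Hmgn5 probe set did not read higher in hearts labelled transgenic. Its log2 value in adults was 8.42 ± 0.25 (SD, n = 3) against 8.57 ± 0.17 (n = 3) in controls, a difference of -0.16 (SE 0.14, limma adjusted p = 0.647). In newborns it was 8.70 ± 0.14 (n = 3) against 8.83 ± 0.03 (n = 2), a difference of -0.13 (SE 0.16, adjusted p = 0.999985). Hmgn5 has 1 probe set here. Affymetrix probe sets lie near the 3′ end of a transcript. The transgene is described as a full-length mouse Hmgn5 cDNA, but the sources used here do not say whether this includes the part that the probe set reads. The probe set therefore does not check the labels, and each direction below rests on the label transgenic. Transgenic hearts also carried a cre recombinase while controls were labelled wild-type, so effects of cre and of Hmgn5 were not tested apart.

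Adult hearts labelled transgenic had 757 genes higher and 533 lower than controls among 18194 tested (limma adjusted p under 0.05), and 331 of the rising and 172 of the falling genes changed more than 2-fold. The cartilage intermediate layer protein gene Cilp rose most, from 5.79 ± 0.87 to 10.58 ± 0.60 (log2, SD, n = 3 each), a log2 fold change of 4.79 (SE 0.38, adjusted p = 8.35e-05). The galectin gene Lgals3 rose by 4.15 (SE 0.29) and the ubiquitin hydrolase gene Uchl1 by 3.66 (SE 0.20). The carboxylesterase gene Ces1d fell by 3.49 (SE 0.24), from 10.31 ± 0.19 to 6.83 ± 0.37. The muscle-specific ribosomal protein gene Rpl3l fell by 2.50 (SE 0.22) and the centromere protein gene Cenpf by 2.52 (SE 0.21). Other genes with the largest rises were Nmrk2 (3.74), Nox4 (3.40), Ltbp2 (3.37), Psca (3.36), Itgbl1 (3.32), Ccn5 (3.19), Postn (3.18), Timp1 (3.15) and Serpina3n (3.12). Other genes with the largest falls were Car3 (-3.28), Ano10 (-2.93), Ttll1 (-2.81), Tbc1d10c (-2.61), Mme (-2.55), Kcnj3 (-2.49), Rbfox1 (-2.38), Ift81 (-2.38) and Kcnd2 (-2.36). Adjusted p of these 24 genes was at most 0.0217, that of Car3. The values of Car3 spread widely, at 8.56 ± 1.73 in controls and 5.28 ± 1.11 in transgenic hearts (SD, n = 3 each). With the 18S batch as a factor 2625 genes were called, and 2183 without it, while replicate 3 alone is 1 array against 1 and has no test. The count fell to 746 without control replicate 2, 373 with the 6 adult arrays alone, whose median residual SD was 0.21 against 0.18 over all arrays, and 238 with atrial markers as a covariate, and rose to 2267 without transgenic replicate 3. The shared spread is thus narrower than that of the adult arrays alone and makes the adult test liberal.

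**Figure D1:**
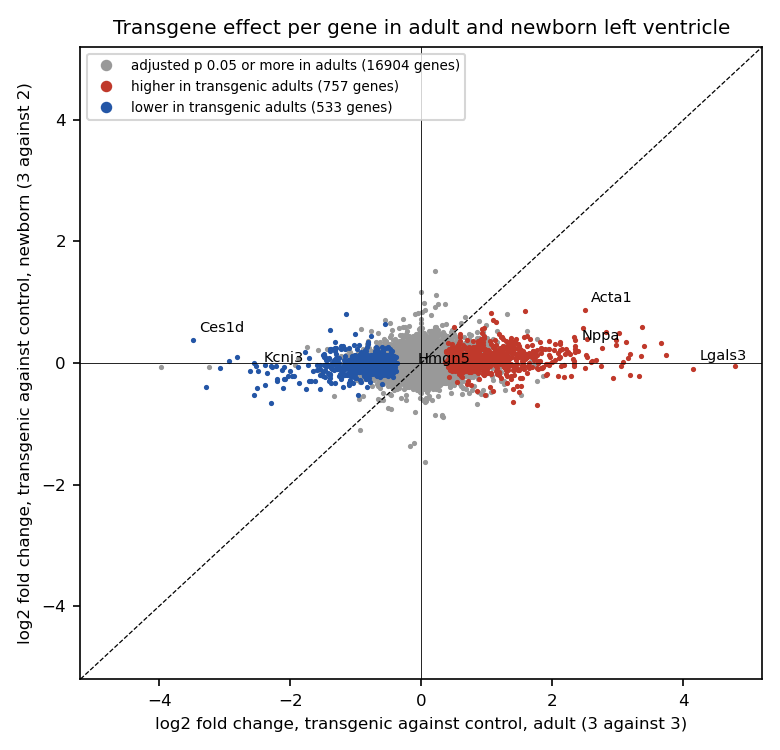
Each point is 1 of 18194 genes, with the log2 fold change of transgenic against control hearts in adults (horizontal) and newborns (vertical), coloured by the adult test; the dashed line marks equal effects. The 757 rising and 533 falling adult genes spread along the horizontal axis and have a median newborn change of 0.08 and -0.03 on the vertical axis.

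Extracellular matrix genes rose together in transgenic adult hearts. Of 37 measured members of the matrix and fibrosis list, 18 rose, 0 fell and 19 did not pass; adjusted over the list alone, 23 rose and 0 fell. Besides Cilp, periostin (Postn) rose from 8.85 ± 0.84 to 12.03 ± 0.46 (SD, n = 3 each). The elastic fibre gene Mfap5 rose by 2.52 (SE 0.25), and the growth factor genes Ccn2 and Tgfb3 by 2.53 (SE 0.26) and 1.97 (SE 0.21). The median change was 1.11 and the list was called by camera (adjusted p = 1.15e-17), but with an adjusted p = 0.185 with an estimated correlation. Markers of fibroblasts and macrophages moved with it. Of 12 fibroblast markers 3 rose and 0 fell (4 and 0 adjusted over the list alone), among them Mfap4 at 2.96 (SE 0.31), and of 17 macrophage markers 4 rose and 0 fell (8 and 1 adjusted over the list alone), among them C1qc at 0.69 (SE 0.15). Both lists were called, with adjusted p = 0.00520 and 6.22e-04, and adjusted p = 0.482 and 0.560 with an estimated correlation, and without control replicate 1 the fibroblast list had adjusted p = 0.0556.

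Genes of the fetal and stress programme, which heart muscle switches on under load, rose in transgenic adults. Of 15 measured members 8 rose and 0 fell; adjusted over the list alone 12 rose and 0 fell. The natriuretic peptide gene Nppa rose from 11.75 ± 0.47 to 14.10 ± 0.07 (SD, n = 3 each), a log2 fold change of 2.35 (SE 0.19, adjusted p = 8.41e-05). Its 3 transgenic values, 14.05 to 14.18, lay near the highest value of any probe set on these arrays, 14.21 to 14.37, so the size of this fold is less certain than its direction. The skeletal actin gene Acta1 rose by 2.49 (SE 0.29) and the slow myosin gene Myh7 by 2.58 (SE 0.53, adjusted p = 0.0147). The list was called with adjusted p = 6.53e-10, and with adjusted p = 0.00770 with an estimated correlation. Immediate early genes rose as well: 4 of 22 rose, 0 fell and 18 did not pass (8 rising adjusted over the list alone), among them Maff at 1.43 (SE 0.27) and Atf3 at 1.41 (SE 0.30). Their adjusted p was 1.32e-04, and adjusted p = 0.0613 with an estimated correlation. Of 19 interferon response genes 3 rose and 0 fell (5 adjusted over the list alone), among them Ifit2 at 1.20 (SE 0.20), with adjusted p = 2.24e-05, and adjusted p = 0.394 with an estimated correlation.

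Genes of mitochondrial fuel use fell in the same hearts. Of 28 fatty acid oxidation genes 13 fell, 0 rose and 15 did not pass; adjusted over the list alone 21 fell. The thiolase gene Acaa2 fell from 12.13 ± 0.18 to 11.00 ± 0.20 (SD, n = 3 each), by 1.14 (SE 0.13, adjusted p = 7.79e-04), and the isomerase gene Eci1 fell by 1.00 (SE 0.15). Ppara, which encodes the nuclear receptor that drives this pathway, fell by 1.26 (SE 0.24). The list was called with adjusted p = 4.03e-14, and adjusted p = 0.311 with an estimated correlation. Of 40 oxidative phosphorylation genes 5 fell and 0 rose (7 falling adjusted over the list alone), among them the complex I gene Ndufs1 by 0.70 (SE 0.11), with adjusted p = 1.27e-10, and adjusted p = 0.0396 with an estimated correlation.

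Ion channel genes fell too. Of 18 measured channel and gap junction genes 8 fell, 0 rose and 10 did not pass, and the count adjusted over the list alone was also 8. Kcnj3, a subunit of the acetylcholine-activated potassium channel, fell from 8.78 ± 0.43 to 6.29 ± 0.11 (SD, n = 3 each), by 2.49 (SE 0.20). Kcnd2 and Kcnip2, which carry and tune the transient outward current, fell by 2.36 (SE 0.32) and 1.27 (SE 0.17), and the sodium channel subunit gene Scn4b by 1.12 (SE 0.17). The list was called with adjusted p = 1.58e-08, and with adjusted p = 0.0153 with an estimated correlation. Markers of the atrium, the neighbouring chamber, differed between arrays in these hearts. The mean of Myl4, Myl7 and Sln was 6.59 and 6.52 in transgenic replicates 2 and 3, 10.53 in transgenic replicate 1 and 10.10 to 12.24 in controls. Of 11 atrial markers 1 rose and 2 fell (1 and 5 adjusted over the list alone). The list was called with adjusted p = 0.00568, adjusted p = 0.394 with an estimated correlation, adjusted p = 0.335 without the 18S batch and adjusted p = 0.173 without control replicate 3. Control replicate 3 also read 7.62 for the brown fat gene Ucp1, against 3.71 to 3.91 in the other adult arrays. The 9 adipocyte markers were called as lower in transgenic hearts, with adjusted p = 0.0230, 1 falling and 0 rising (2 and 1 adjusted over the list alone), and adjusted p = 0.311 with an estimated correlation. Without control replicate 3 or transgenic replicate 1 or 2 the adipocyte list was not called (adjusted p = 0.0849, 0.100 and 0.105).

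**Figure D2:**
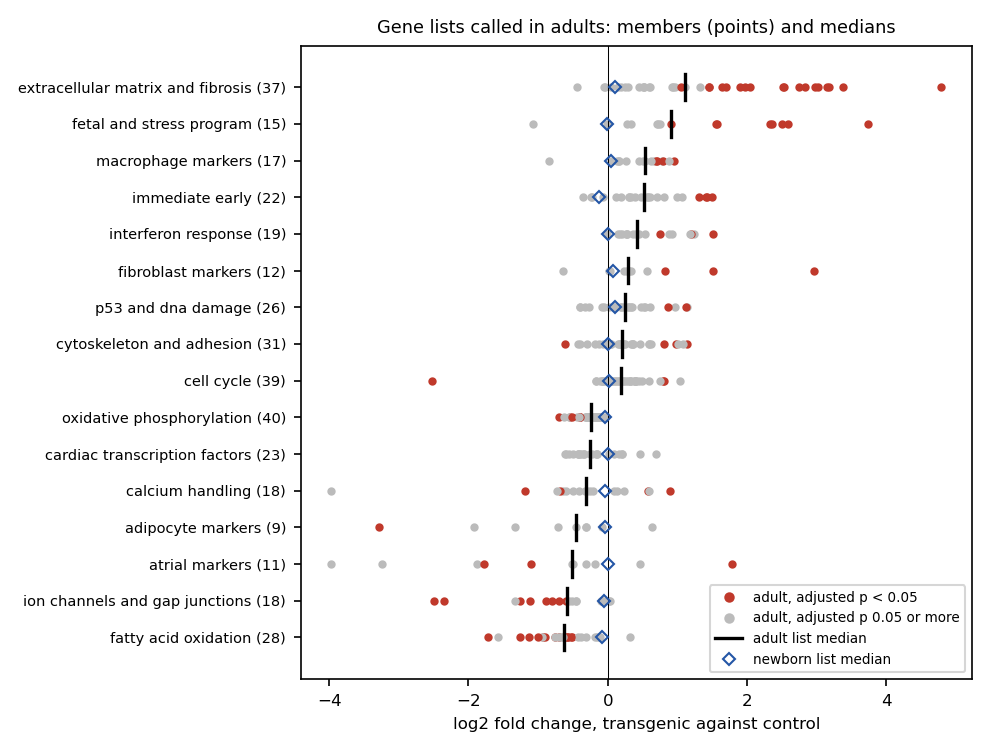
Each row is 1 of the 16 gene lists called in adults, with the number of measured genes in brackets; points are members at their adult log2 fold change (horizontal axis), black bars the adult medians and open diamonds the newborn medians. Adult medians run from -0.63 for fatty acid oxidation to 1.11 for the matrix list, while the newborn medians of the same pair are -0.08 and 0.11.

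Chromatin and nuclear envelope genes are the closest to the known role of HMGN5. Of 26 nuclear lamina and envelope genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), where 7.09% of all tested genes were called. The nuclear pore gene Nup50 rose by 0.83 (SE 0.11), the envelope gene Tmem43 by 1.08 (SE 0.17) and the lamin A gene Lmna by 0.86 (SE 0.22, adjusted p = 0.0439), while the nesprin gene Syne2 fell by 0.92 (SE 0.20). The median was 0.01 and the list was not called as moving in 1 direction (adjusted p = 0.945). Of 30 chromatin architecture genes 2 rose and 0 fell, also adjusted over the list alone: Hmgn3, of the same family as the transgene, at 1.58 (SE 0.30) and Hmgb2 at 0.72 (SE 0.16). The list was not called (adjusted p = 0.658). Of 3 measured linker histone genes H1f2 rose by 1.06 (SE 0.19), the count adjusted over the list alone was also 1, and the list was not called (adjusted p = 0.240).

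Cytoskeleton and adhesion genes were called as higher (3 rising and 1 falling of 31, 9 and 1 adjusted over the list alone, adjusted p = 0.0159, and adjusted p = 0.311 with an estimated correlation), with Zyx at 1.13 (SE 0.18). Genes of the p53 response were called as higher (2 rising and 0 falling of 26, the same adjusted over the list alone, adjusted p = 0.0299, and adjusted p = 0.311 with an estimated correlation), but not without the 18S batch (adjusted p = 0.207). Cell cycle genes were called as higher (2 rising and 1 falling of 39, the same adjusted over the list alone, adjusted p = 0.0422, and adjusted p = 0.930 with an estimated correlation). Calcium handling genes were called as lower (2 rising and 2 falling of 18, 3 and 3 adjusted over the list alone, adjusted p = 0.0488, and adjusted p = 0.394 with an estimated correlation), with the calcium store gene Hrc at -1.19 (SE 0.10). Cardiac transcription factors were called as lower with 0 of 23 members passing, also adjusted over the list alone (adjusted p = 0.0488, and adjusted p = 0.723 with an estimated correlation). Of the 16 lists called in adults, 16 were called with the 18S batch as a factor, 14 without that batch, 12 with the atrial covariate, 11 with the filter on low values, 12 without transgenic replicate 1 or 2 and 11 without control replicate 2 or 3. Calcium handling, cardiac transcription factors and cell cycle genes lost the call without each of these 4 arrays, with adjusted p from 0.103 to 0.243, 0.103 to 0.656 and 0.175 to 0.420, and were called in 14, 15 and 17 of 23 settings. The first pair also lost it without either newborn control (adjusted p = 0.0508), and calcium handling without transgenic newborn replicate 3 (adjusted p = 0.0537). Cytoskeleton genes lost it without control replicate 1 or 2 or transgenic replicate 3 (adjusted p = 0.182, 0.0801 and 0.142), and p53 genes without control replicate 2 or transgenic replicate 3 (adjusted p = 0.103 and 0.284). The lists of adult sarcomere genes, glycolysis, endoplasmic reticulum stress, heat shock, hormone signalling, the circadian clock and fetal isoforms were not called, with adjusted p from 0.493 to 0.997. Neither were markers of endothelial, mural, lymphoid, neutrophil, erythroid, epicardial, neural and skeletal muscle cells or of thymus and lung, with adjusted p from 0.359 to 0.995.

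In newborn hearts no single gene passed the test between transgenic and control. With limma, 0 of 18194 genes were called, the smallest adjusted p was 0.999985 and 198 genes had an unadjusted p under 0.05, where chance alone gives 909.7. The shared spread (median residual SD 0.18) was wider than that of the newborn arrays alone (0.11), with which 0 genes were called and 910 had an unadjusted p under 0.05. The rising genes with the smallest p were Sfrp5 at 0.65 (SE 0.13), Prkg2 at 0.92 (SE 0.20), Spaca1 at 0.60 (SE 0.14), Acsl6 at 0.97 (SE 0.25) and Ovgp1 at 0.73 (SE 0.19). The falling genes with the smallest p were Hrc at -0.39 (SE 0.11), Ctxn1 at -0.47 (SE 0.15), Ankrd23 at -0.53 (SE 0.17), Xlr4c at -0.36 (SE 0.12) and Prss50 at -0.42 (SE 0.14), and none of these 10 passed. Cilp read 3.89 ± 0.09 (n = 3) against 3.95 ± 0.06 (n = 2) and Nppa 13.78 ± 0.08 (n = 3) against 13.55 ± 0.01 (n = 2). The median 95% interval of a gene's newborn change reached 0.37 to either side on the log2 scale, and in newborn data simulated with the shared spread 19.4% of 1.5-fold and 71.6% of 2-fold changes were recovered. Of the 35 lists 7 were called, each with 0 members passing, also adjusted over the list alone, against 13 with the replicate block and 4 with cyclic loess. Higher were endoplasmic reticulum stress (29 genes, median 0.10, adjusted p = 8.20e-04), epicardial markers (9 genes, median 0.30, adjusted p = 0.00196) and circadian clock genes (17 genes, median 0.11, adjusted p = 0.0457), each with adjusted p = 0.509 with an estimated correlation. Lower were immediate early genes (22 genes, median -0.12, adjusted p = 0.00297), erythroid markers (11 genes, median -0.17, adjusted p = 0.00446), oxidative phosphorylation (40 genes, median -0.04) and fatty acid oxidation (28 genes, median -0.08), the last 2 with adjusted p = 0.0310 each. For these 4, adjusted p was 0.427, 0.427, 0.509 and 0.890 with an estimated correlation, and fry called 0 lists. Without transgenic newborn replicate 1, 3 lists were called: epicardial (adjusted p = 0.784), erythroid (0.0891), oxidative phosphorylation (0.365) and fatty acid oxidation (0.169) lost the call, the epicardial list with its direction turned. Without control newborn replicate 2, 3 lists were also called: epicardial (0.149), circadian (0.877), oxidative phosphorylation (0.451) and fatty acid oxidation (0.880) lost it, the last with its direction turned. Without transgenic newborn replicate 2, circadian (0.290), oxidative phosphorylation (0.138) and fatty acid oxidation (0.290) lost it, without control newborn replicate 1 immediate early genes (0.214) and erythroid markers (0.0897), and without transgenic newborn replicate 3 immediate early and circadian genes (0.0618 each). Circadian genes also lost it without transgenic or control adult replicate 1 (0.0655 and 0.0627), and were called in 14 of 22 settings. The matrix list, not called in newborns (adjusted p = 0.0514), was called in 13 of 22.

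The effect of the transgene label differed between ages for 125 genes, 81 with a higher and 44 with a lower effect in adults (limma, adjusted p under 0.05). All 125 were also called in adults in the same direction. The largest differences in log2 fold change were those of Cilp (4.84, SE 0.57), Lgals3 (4.25, SE 0.43), Nmrk2 (3.61, SE 0.54), Itgbl1 (3.55, SE 0.41), Ccn5 (3.38, SE 0.50) and Uchl1 (3.32, SE 0.30) upwards. Downwards they were Ces1d (-3.87, SE 0.37), Ano10 (-2.96, SE 0.41), Ttll1 (-2.91, SE 0.33), Tbc1d10c (-2.48, SE 0.36), Cenpf (-2.47, SE 0.32) and Kcnj3 (-2.37, SE 0.29). In newborns Lgals3 read 7.83 ± 0.57 (SD, n = 3) in transgenic and 7.92 ± 0.13 (n = 2) in control hearts, between the values of the adult groups, 9.96 ± 0.23 and 5.81 ± 0.48 (n = 3 each). Of the 35 lists 11 were called, the fetal and stress programme, ion channels and immediate early genes holding with an estimated correlation (adjusted p = 0.00494, 0.0135 and 0.0276). With the 18S batch as a factor 494 genes were called, and 711 without it. The count was 6 and 35 without control newborn replicate 1 and 2, 73, 48 and 39 without transgenic newborn replicate 1, 2 and 3, 79 and 540 without transgenic adult replicate 1 and 3, 202 and 59 without control adult replicate 1 and 2, 841 with array weights and 10 with the atrial covariate.

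**Figure D3:**
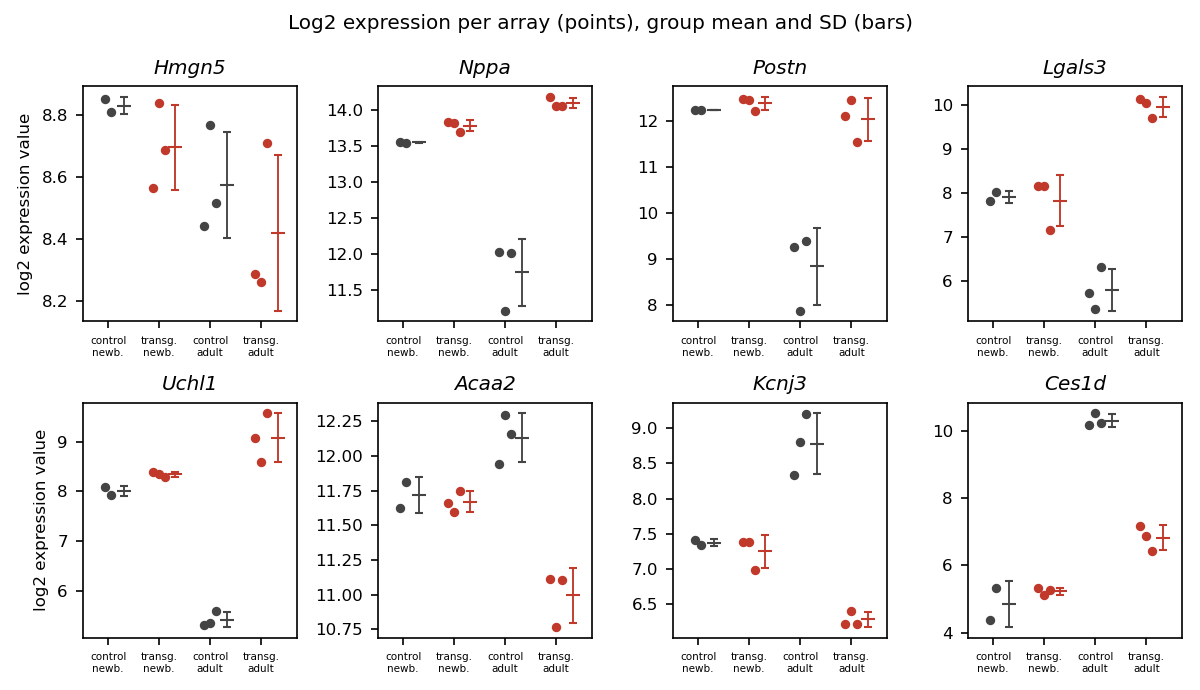
Log2 expression of 8 genes on each of 11 arrays (points), with group mean and SD (bars), for newborn and adult control (grey) and transgenic (red) hearts; each panel has its own vertical axis, which does not start at 0. Nppa, Postn, Lgals3 and Uchl1 are higher and Acaa2, Kcnj3 and Ces1d lower on all 3 transgenic adult arrays than on all 3 control adult arrays, while Hmgn5 overlaps.

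Control hearts differed widely between ages: 2718 genes were higher and 3288 lower in adults. The slow skeletal troponin gene Tnni1 fell most, from 13.55 (n = 2) to 5.36 ± 0.16 (SD, n = 3), a log2 fold change of -8.19 (SE 0.18, adjusted p = 1.75e-09). Falling with it were the cell division genes Ube2c (-6.26), Birc5 (-6.02), Ccnb2 (-5.63) and Rrm2 (-5.50), the imprinted gene Mest (-5.72), Bex4 (-5.62) and Cited1 (-5.35). The largest rises were those of Ces1d (5.47), Rpl3l (5.41), Plet1os (5.35), the Z-disc gene Myot (4.76), Tuba8 (4.67), Asb14 (4.50), Asb15 (4.24) and Smco1 (3.81). Of 39 cell cycle genes 33 were lower and 0 higher in adults (35 lower adjusted over the list alone), with adjusted p = 3.15e-27, and adjusted p = 0.147 with an estimated correlation. Of 30 chromatin architecture genes 21 were lower and 0 higher (22 lower adjusted over the list alone), led by Hmgb2 at -4.21 (SE 0.18), with adjusted p = 2.62e-08, and with adjusted p = 0.0164 with an estimated correlation. Of 28 fatty acid oxidation genes 18 were higher and 2 lower (20 and 2 adjusted over the list alone), among them Cpt2 at 1.64 (SE 0.19), with adjusted p = 5.81e-05, and adjusted p = 0.462 with an estimated correlation. Of 37 matrix genes 23 were lower and 1 higher, also adjusted over the list alone, among them Fn1 at -3.60 (SE 0.34), with adjusted p = 2.23e-08, and adjusted p = 0.346 with an estimated correlation. The count of called genes was 2829 and 3654 without control newborn replicate 1 and 2.

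Transgenic hearts differed between ages as widely, with 3579 genes higher and 3582 lower in adults. Cilp was higher in adults by the most, 6.69 (SE 0.38), followed by Plet1os (6.00), the apolipoprotein gene Apod (5.76), Itgbl1 (4.99), Cpxm2 (4.68), Myot (4.61), Serpina3n (4.14) and Pi16 (3.98). Tnni1 fell most, by 7.79 (SE 0.16), followed by Mest (-5.98), Nrk (-5.49), the atrial light chain gene Myl7 (-5.47, SE 0.92), Ube2c (-5.22), the growth factor gene Igf2 (-5.22), Ccnb2 (-5.15) and Cited1 (-5.05). Of 28 fatty acid oxidation genes 6 were higher and 4 lower, also adjusted over the list alone, and the list was not called (adjusted p = 0.693). Of 37 matrix genes 10 were higher and 15 lower (10 and 17 adjusted over the list alone), and this list was not called either (adjusted p = 0.159). Cell cycle genes were lower, 35 of 39 with 0 higher, also adjusted over the list alone (adjusted p = 1.67e-26, and adjusted p = 0.222 with an estimated correlation). The same direction was called in control and transgenic hearts for 1746 rising and 2565 falling genes, where independent lists would share 534.7 and 647.3. These age contrasts share no arrays. The count of called genes was 1828 with the atrial covariate and 4359 with the 1.5-fold threshold. The mean of Myl4, Myl7 and Sln was 12.5 to 12.9 on newborn arrays. It was 10.10 to 12.24 in adult controls and 6.52 to 10.53 in transgenic adults. Age and atrial content were not tested apart in either age contrast.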

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

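The tests of the newborn sample size and of Hmgn5 in this part were chosen only after the results were seen. So were the fits with or without the 18S batch, the atrial covariate and the separate controls. Bounds for the fold ratio of the replicate 3 arrays were written before that ratio was seen, but a further condition was added after first values were seen.

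The effect of the transgene label differed between adult and newborn hearts for 125 genes by the test of the difference itself. Cilp differed by 4.84 on the log2 scale, Lgals3 by 4.25, Nmrk2 by 3.61, Itgbl1 by 3.55, Ccn5 by 3.38 and Uchl1 by 3.32. In the other direction, Ces1d differed by -3.87, Ano10 by -2.96, Ttll1 by -2.91, Tbc1d10c by -2.48, Cenpf by -2.47 and Kcnj3 by -2.37. The median difference was 0.98 for the fetal and stress programme, 0.96 for matrix genes, 0.68 for immediate early genes, 0.56 for macrophage markers, 0.44 for interferon response genes, 0.32 for fibroblast markers and 0.20 for cytoskeleton and adhesion genes. It was -0.73 for atrial markers, -0.64 for ion channels, -0.52 for fatty acid oxidation and -0.19 for oxidative phosphorylation. Adjusted p of these 11 lists was at most 0.0221, but 8 of them were not called with an estimated correlation. Their adjusted p with an estimated correlation was 0.234 for matrix genes, 0.643 for macrophage and fibroblast markers, 0.533 for interferon response genes and atrial markers, 0.482 for cytoskeleton and adhesion genes and fatty acid oxidation, and 0.108 for oxidative phosphorylation. Without control newborn replicate 1, 8 lists were called, and cytoskeleton genes (adjusted p = 0.124), fibroblast (0.186) and macrophage markers (0.139) lost the call. Without transgenic adult replicate 2, fibroblast (0.0999), macrophage and atrial markers (0.0537 each) lost it, and without control adult replicate 3 atrial markers (0.299). Cytoskeleton genes and fibroblast markers lost it without control adult replicate 1 (0.182 and 0.176) or 2 (0.0794 each), cytoskeleton genes without transgenic adult replicate 3 (0.129) and fibroblast markers without transgenic newborn replicate 3 (0.124).

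The 18S batch and the atrial markers both differ among the arrays behind the 1290 adult calls. Without that batch, 2183 genes were called, 1117 of the 1290 among them, which argues against the batch as the whole source. That fit shares the narrower newborn spread and is liberal. Of the 2183 genes, 1800 moved the same way between the 2 replicate 3 arrays, with a median fold 0.700 of that in replicates 1 and 2. This ratio rests on 1 array against 1 and decides nothing about the batch, because the batch had no part in those calls. With atrial markers as a covariate, all 1290 genes kept their direction, with a median log2 fold change of 0.93 (median SE 0.24) against 0.92 (SE 0.17) without it for the 757 rising genes, a ratio of 1.01, and of -0.79 (SE 0.23) against -0.81 (SE 0.16) for the 533 falling genes, a ratio of 0.975. Of these, 160 and 74 were still called, and the other 597 and 459 lost the call mainly because the SE widened (median 0.79, SE 0.24, against 0.84, SE 0.17, and -0.73, SE 0.23, against -0.75, SE 0.16), although Serpina3n moved from 3.12 to 2.07 and Car3 from -3.28 to -1.95. On transgenic replicate 1, with atrial markers at the control level, genes called without it had a median fold 0.928 (538 rising) and 0.880 (374 falling) of that in replicates 2 and 3, over the 0.5 set in advance as excluding atrial tissue, but this rests on 1 array and on controls shared with the calls, and with separate controls the ratio was 0.697 to 0.925 and 0.517 to 1.04. The covariate acts through the spread within groups, which is widest in transgenic adults (10.53, 6.59 and 6.52), so the covariate rests largely on the same array. The 1290 genes were also chosen by the fit without the covariate, which favours a ratio near 1. Neither test therefore decides whether less atrial tissue is the whole source. A part of single folds stays open too, as do the 11 atrial markers, 2 of them also in other lists and 10 above the 40th percentile on every array.

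The 6 adult arrays can be split in 10 ways, too few for a share under 0.05. The real split called 1290 genes (1 of 10 with as many), and the highest of the others, with transgenic replicate 3 and control replicate 1 exchanged, called 829. The 6 transgenic arrays can also be split in 10 ways, with 7161 genes for adult against newborn (1 of 10 with as many) and 0 for the highest of the others.

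The number of arrays is a candidate source of the 0 calls in newborns. With 1 control array left out, which makes it 3 against 2 as in newborns, adult hearts still gave at least 746 calls. These adult fits share the narrower newborn spread, which makes them liberal. With the adult arrays alone, 3 against 3 gave 373 calls, and 3 against 2 was not run. The calls therefore argue only weakly against the number of arrays, and only where differences are as large as in adults. Smaller differences stay open, since the shared spread (median residual SD 0.18) is wider than that of the newborn arrays alone (0.11) and makes the newborn test conservative. It gave 198 genes at an unadjusted p under 0.05, where chance alone gives 909.7, against 910 with the newborn arrays alone and 1076 with array weights, and limma called 0 genes in each. The ages differ in biology and may differ in array processing, which were not tested apart.

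The Hmgn5 probe set differed by -0.16 in adults and by -0.13 in newborns. A transgene without the part that the probe set reads, although described as a full-length cDNA, or hearts without a raised transcript, could each give these values. They cannot be told apart, because the position of the probes in the transcript was not analysed here. The 1290 adult calls show that the adult groups differ, not that Hmgn5 was raised.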

How the results depend on the processing

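The settings with the 18S batch, the atrial covariate, sex and the block in adult arrays alone were chosen after seeing the data; the others were fixed before. Of 198 alternative counts that answer comparisons, 163 lay within 1.5 times and 35 moved, and the cause was not tested unless stated. A count within 1.5 times need not hold the same genes. Of the 1290 adult calls, 63.9% were kept without transgenic adult replicate 1, 76.0% with the mean of probe sets and 97.9% with cyclic loess. The Hmgn5 difference was negative and did not pass the test in 49 alternatives, from -0.33 to -0.06 in adults and -0.20 to -0.07 in newborns. The newborn count was 0 under every setting run, with 138 to 1076 genes at an unadjusted p under 0.05. Adult calls (1290) moved to 373 with only the compared groups, which leaves fewer arrays and also drops the smaller newborn spread, 2625 with the 18S batch as a factor, 2183 without it and 238 with the atrial covariate. Difference calls (125) moved to 841 with array weights, 494 with the batch as a factor, 711 without it and 10 with the atrial covariate. Age calls in transgenic hearts (7161) moved to 1828 with the atrial covariate and 4359 with the 1.5-fold threshold, which removes small changes by construction. Leaving out each array gave 746 to 2267 adult, 6 to 540 difference, 2829 to 7430 control age and 4971 to 7981 transgenic age calls; leaving out a newborn control leaves 1 array, taken to vary like the other groups. Called lists moved in adults from 16 to 3 with an estimated correlation and 10 with fry, and for the difference from 11 to 3 and 4. In newborns they moved from 7 to 13 with the replicate block, 4 with cyclic loess, 0 with an estimated correlation and 0 with fry, and to 3 to 10 without 1 array. Of 832 list values 131 lost the call and 2 reversed: newborn fatty acid oxidation without control newborn replicate 2 (adjusted p = 0.880, lowest 5.43e-05 without another array) and newborn epicardial markers without transgenic newborn replicate 1 (adjusted p = 0.784, lowest 4.86e-07). Of 3908 values of named genes 447 lost the call and 0 reversed. Of the lost calls, 417 were among 2625 values of the adult transgenic against control contrast. There, 31 of 105 named genes kept the call in every setting that tested them. The 3908 include 239 newborn values of genes that were not called in the main fit and so had no call to lose.

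Groups share replicate numbers, with no source saying that a number marks a pair. Same-numbered adult arrays did share traits: replicate 1 was male in both groups, and replicate 3 stood apart in both. Besides 18S and Malat1, replicate 3 read higher for the DapX spike-in control (8.04 and 7.37, against 5.15 to 6.34 in the other adult arrays). The clock gene Dbp was lower there (8.43 and 7.61, against 10.27 to 10.69) and Arntl higher (7.67 and 8.31, against 5.39 to 6.24). The cause was not tested. Deviations of same-numbered adult arrays from their group means correlated at 0.31, -0.06 and 0.45 over the tested genes, so not every pair was over 0.1, but at 0.43, 0.15 and 0.64 over all probe sets, so the answer depends on which of them are used. This choice was not blind: counts with the block had been seen by then. With the replicate block 1466 adult genes were called, 1209 of them among the 1290, and in adult arrays alone 676 with the block against 373 without it. Adult replicates 1 and 3, but not 2, correlated best with their own number; newborn pairs gave 0.18 and -0.15. The signal of an array over background was not analysed here, so values near either end of the scale are less certain.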

Other observations

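The tests with separate adult controls and the exact permutation test in this part were chosen only after the results were seen.

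Several cell type markers that the comparisons above do not describe differed between adult and newborn arrays, where age and array processing cannot be told apart. In control hearts 13 of 17 macrophage markers were higher in adults than in newborns and 0 lower (17 adjusted over the list alone), among them Lyz2 at 2.62 (SE 0.21) and Cd74 at 2.97 (SE 0.33), and in transgenic hearts all 17 were higher. Of 9 epicardial markers 8 were lower in adults and 0 higher, also adjusted over the list alone, with Msln at -3.09 (SE 0.23) and Wt1 at -1.38 (SE 0.18). Of 23 cardiac transcription factors 11 were lower and 4 higher (12 and 4 adjusted over the list alone), led by Hey2 at -3.60 (SE 0.20). The lists were called by camera with adjusted p = 1.37e-07, 5.90e-05 and 0.0115, and had adjusted p = 0.346, 0.346 and 0.462 with an estimated correlation. Fetal isoforms and imprinted growth genes were lower in adults too, 11 of 15 lower and 0 higher, also adjusted over the list alone, with Dlk1 at -3.87 (SE 0.12) and Igf2 at -4.40 (SE 0.25), and this list held with an estimated correlation (adjusted p = 0.0117).

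In transgenic hearts 10 of 19 interferon response genes were higher in adults than in newborns and 0 lower (14 adjusted over the list alone), with Ifit3 at 2.20 (SE 0.28) and Ifit1 at 2.79 (SE 0.43). In control hearts 5 were higher and 0 lower, also adjusted over the list alone. The list was called in transgenic hearts (adjusted p = 1.62e-04, and adjusted p = 0.427 with an estimated correlation) but not in control hearts (adjusted p = 0.160). The difference between these age effects equals the difference of the transgene effect, for which the list was called with adjusted p = 5.09e-05, and had adjusted p = 0.533 with an estimated correlation.

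A hypothesis is that adult transgenic hearts return in part towards newborn levels. Of the 757 genes rising in adults, 400 were also higher in newborn than in adult controls and 63 lower, where independent lists would share 136.8 and 113.1. Of the 533 falling genes 329 were also lower in newborn controls and 32 higher, where independent lists would share 79.6 and 96.3. Both contrasts use the adult controls, which alone gives a correlation of 0.447 across genes in simulated unchanged groups, against 0.342 observed. The covariance, which shared controls add to equally with or without effects, was 0.106 against 0.0210 simulated, a difference of 0.0849 with a simulated SD of 0.00112 that takes genes as independent and is too small. With 1 adult control in 1 contrast and the other 2 in the other, the covariance was 0.0554 to 0.0983 over the 3 ways. The values are consistent with a partial return, but part of the excess may come from the shared controls. Other genes moved away from newborn levels or did not pass in adults. Cilp read 3.95 in newborn controls, 5.79 in adult controls and 10.58 in transgenic adults, and macrophage markers, of which 13 of 17 were lower in newborn controls, rose in 4 cases and fell in 0. Tnni1 did not pass (0.33, SE 0.16, adjusted p = 0.285).

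A second hypothesis is that the adult differences are already present in newborn hearts at a smaller size. Of the 757 genes rising in adults 530 had a positive newborn difference, and of the 533 falling genes 326 a negative one. Signed by the adult direction, the newborn difference of these genes averaged 0.057 on the log2 scale, and 4 of the 10 splits of the newborn arrays into 3 and 2 gave one at least as large (2-sided exact permutation p = 0.4, where 0.1 is the smallest possible). The fry test, a rotation test and not an exact one, gave p = 0.404 for the 1290 genes. A fry p of at least 0.05 had been set in advance as counting against this hypothesis, but that bound was wrong, because a p that misses a threshold does not exclude a small effect. This was decided after the value was seen, and the hypothesis stays open.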
